A study of Mus musculus with 16 samples.

How the data were processed

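The series compares gene expression in kidney between wild-type (WT) mice and mice labelled C3-/-, each given glycerol to induce rhabdomyolysis or given PBS. RNA from lysed frozen sections of 30 µm was sequenced in 16 libraries, 4 per group, with standard Illumina library protocols per the labels' protocols. The groups and replicate numbers were taken from the sample titles.

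The authors deposited 1 matrix of gene-level signal, in which each value is a read count that the authors had normalized with DESeq2, for 20525 genes in all 16 libraries. Per the submitters' processing notes, STAR 2.7.1, DESeq2 and R 3.6.1 were used with genome build GRCm38, and per the file headers the gene models came from Ensembl release 96. The program that counted reads, its strand setting and its treatment of reads matching several genes are not given in the sources used here. Near-identical gene copies, and genes that overlap on opposite strands, may therefore share reads, and 37 genes had all 16 values equal to those of another gene. The authors also deposited 3 tables of their own comparisons, with a log2 fold change, its standard error, a p-value and an adjusted p-value per gene: WT glycerol against PBS, C3-/- glycerol against PBS, and glycerol C3-/- against WT. In each table the mean signal listed by the authors equalled the mean of the 16 deposited columns.

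A search for the size of 1 read was made in every column before any test. Between 1.8% and 2.1% of the values in a library were whole multiples of its lowest value within a tolerance of 0.01, so whole reads were not recovered, the sequencing depth is unknown, and no count model was run here. No interval based on counting error can be given. The precision of every value rests on the spread between the 4 libraries of a group.

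Values were tested as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3. Genes with a normalized count of at least 10 in at least 4 libraries entered the test, which left 18035. All 16 libraries were fitted together with 1 coefficient per group, and the moderated two-sided test used a mean-variance trend. The 5 contrasts were glycerol against PBS in WT, glycerol against PBS in libraries labelled C3-/-, the genotypes after glycerol, the genotypes after PBS, and the difference between the 2 glycerol responses (the interaction). Adjusted p-values are Benjamini-Hochberg values over all tested genes of a contrast, and a gene was called at an adjusted p below 0.05. A fold change on the log2(value + 1) scale understates the change of a gene with low values. No fold change of glycerol over PBS is given for a gene listed at 0 in every PBS library of the genotype.

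Gene lists were written before the data were examined: 31 lists covering injury, heme handling, complement, cytokines, stress responses, nephron segments, immune and other cell types, the circadian clock and the sex chromosomes. A list was tested against all other genes with camera from limma when at least 3 members were tested, which held for 30 lists, with a preset correlation between genes of 0.01 and with a correlation estimated from the residuals as a check. Benjamini-Hochberg adjustment was made over the lists of a contrast. Beside it stand the numbers of members called over all genes and when adjusted over the list alone. For C3-/- glycerol against PBS the calls of 5 lists held with the estimated correlation, for glycerol C3-/- against WT those of 2, for PBS C3-/- against WT those of 4, and for the other 2 contrasts no list call held.

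The rule for genes named in the text was also fixed before the data were examined. C3 comes first. Each comparison may name the 8 called genes with the largest rise and the 8 with the largest fall, among those with a mean normalized count of at least 50 and groups of values that do not overlap (the last was not asked of the interaction). It may name up to 4 members of each described list with the smallest p, and a fixed set of injury, complement and cell-type genes including Havcr1, Lcn2, Hmox1, Timp1, Il6 and Umod in any comparison. Predicted genes and gene models without a symbol were counted but not named. Gene positions are from GENCODE M21, the GRCm38 annotation that matches Ensembl release 96, which held 20515 of the 20525 genes.

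The calculations were tested on simulated data made from the mean and spread of each gene. In the simulated WT comparison limma recovered 4.7% of genes changed 1.5-fold, 20% of those changed 2-fold and 56.9% of those changed 4-fold, among 17455 genes, and 3.6% of its calls were unchanged genes. In the simulated interaction, over 17463 genes, the shares were 0%, 7.7% and 34.4%. Small changes were thus often missed in this setting. Few genes were changed in it (for WT 64 by 1.5-fold, 65 by 2-fold and 65 by 4-fold), which makes the adjusted threshold stricter. Every simulated library also had the same spread per gene, taken from the pooled fit with list 2 included. The shares are therefore not the power of the real comparisons.

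Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter and a filter on a mean of at least 100, scaling by trimmed means and by quantiles, array weights, a fit of the compared groups only, the replicate number as a block, a term for the sample-sheet list, leaving out list 2, and leaving out each library. Fits with a term for Y-linked transcripts (a normalized count of Ddx3y of at least 100), with that term and the sheet list together, with that term after leaving out list 2, and of the libraries with Y-linked transcripts alone were added after the data had been seen. Values for list 1 in the report come from the fit without the 3 list 2 libraries, and values adjusted for list and sex from the fit with both terms.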

Results

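Kidney gene expression was measured by RNA sequencing of lysates of frozen sections, 30 µm thick, from mice aged 8 weeks whose background the labels give as C56BL/6. The mice were WT or carried the C3-/- genotype, which targets complement component C3, the protein on which the activation pathways of complement converge. Rhabdomyolysis, a breakdown of skeletal muscle that releases heme proteins and can injure the kidney, was induced by injecting 7.5 ml/kg of 50% glycerol into thigh muscle. Control mice received PBS. The 4 groups (WT PBS, WT glycerol, C3-/- PBS and C3-/- glycerol) held 4 libraries each. The labels give neither the sex of the mice nor the time between injection and sampling. They do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

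The deposited normalized counts summed to between 25.81 M and 38.39 M per library over 20525 genes. The number of reads behind them is unknown because whole reads were not recovered from the values. Between 190 and 982 genes were listed at 0 in 15 of the libraries, and 3374 in WT glycerol replicate 4.

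The libraries also differed in 2 ways that cross the groups. The sample descriptions carry sheet numbers that run from 1 to 13 over 13 libraries (list 1). The other 3 libraries, WT glycerol replicate 4 and C3-/- glycerol replicates 1 and 3, repeat the numbers 3, 4 and 5 (list 2), and all PBS libraries were in list 1. On the first principal component, with 45% of the variance, the list 2 libraries had scores of 220.4, 143.6 and 96.4, against -58.6 to 39.5 in list 1. Ddx3y, an RNA helicase gene on the Y chromosome, had normalized counts of 481.5 to 2302.1 in 11 libraries: all 8 WT libraries, C3-/- PBS replicate 4 and C3-/- glycerol replicates 3 and 4. The other 5 libraries labelled C3-/- had at most 1.1, with Xist, the RNA of the inactive X chromosome, between 16098 and 35409.9. Each C3-/- group thus mixed libraries from more than 1 animal, and whether all libraries came from separate animals stays open. Because of these differences, counts of calls are also given within list 1 and with adjustment for list and Y-linked transcripts. List 1 is a part of the libraries from which the named genes were chosen. In any comparison, direction and call kept there by named genes are thus no independent support. For the gene lists described, results from these fits are given where they changed a call or moved the median of a called list by over 1.5 times.

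**Figure D1:**
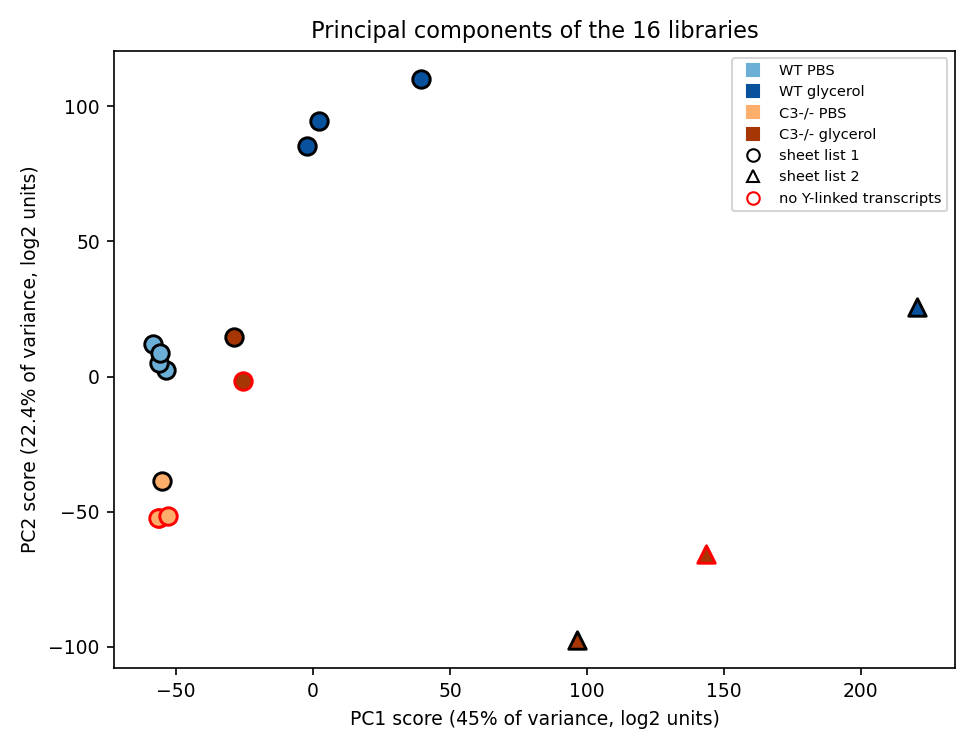
Scores of the 16 libraries on the first (45% of the variance) and second (22.4%) principal components of the log2 values, 1 point per library, with colour for group, shape for sheet list and a red edge where Y-linked transcripts were absent. The 3 list 2 libraries lie at 96.4 or above on the first component, and list 1 WT glycerol libraries lie at 85.5 or above on the second.

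C3 itself (ENSMUSG00000024164; GRCm38 chromosome 17, 57203970 to 57228136) was not lower in the libraries labelled C3-/-. Its normalized count was 397.9 ± 61.4 (SD, n = 4) in WT PBS and 845.7 ± 235.8 (n = 4) in C3-/- PBS, a log2 difference of 1.05 ± 0.48 (SE) with a limma adjusted p of 0.442 (0.00968 within list 1). After glycerol it was 3235 ± 1287 (n = 4) in WT and 4137 ± 3189 (n = 4) in libraries labelled C3-/-, a log2 difference of 0.07 ± 0.48 (adjusted p = 0.95; -0.78 with adjusted p = 0.0721 within list 1). The part of the gene removed in the C3-/- line is not given in the sources used here, so the total signal of the gene cannot check the genotype label, and every direction given below for C3-/- rests on the labels. C3 rose after glycerol in WT by a log2 fold change of 2.94 ± 0.48 (limma adjusted p = 0.000527; 2.72 within list 1). In libraries labelled C3-/- it rose by 1.95 ± 0.48 (adjusted p = 0.0268), and within list 1 by 0.89 (adjusted p = 0.0434), where the 2 glycerol libraries had 1457.3 and 1587.2 against 8008 and 5495.3 in list 2. That call ended without C3-/- PBS replicates 1, 3 or 4 (adjusted p = 0.073, 0.067 and 0.077) and without C3-/- glycerol replicates 1 or 3 (0.084 and 0.06).

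**Figure D2:**
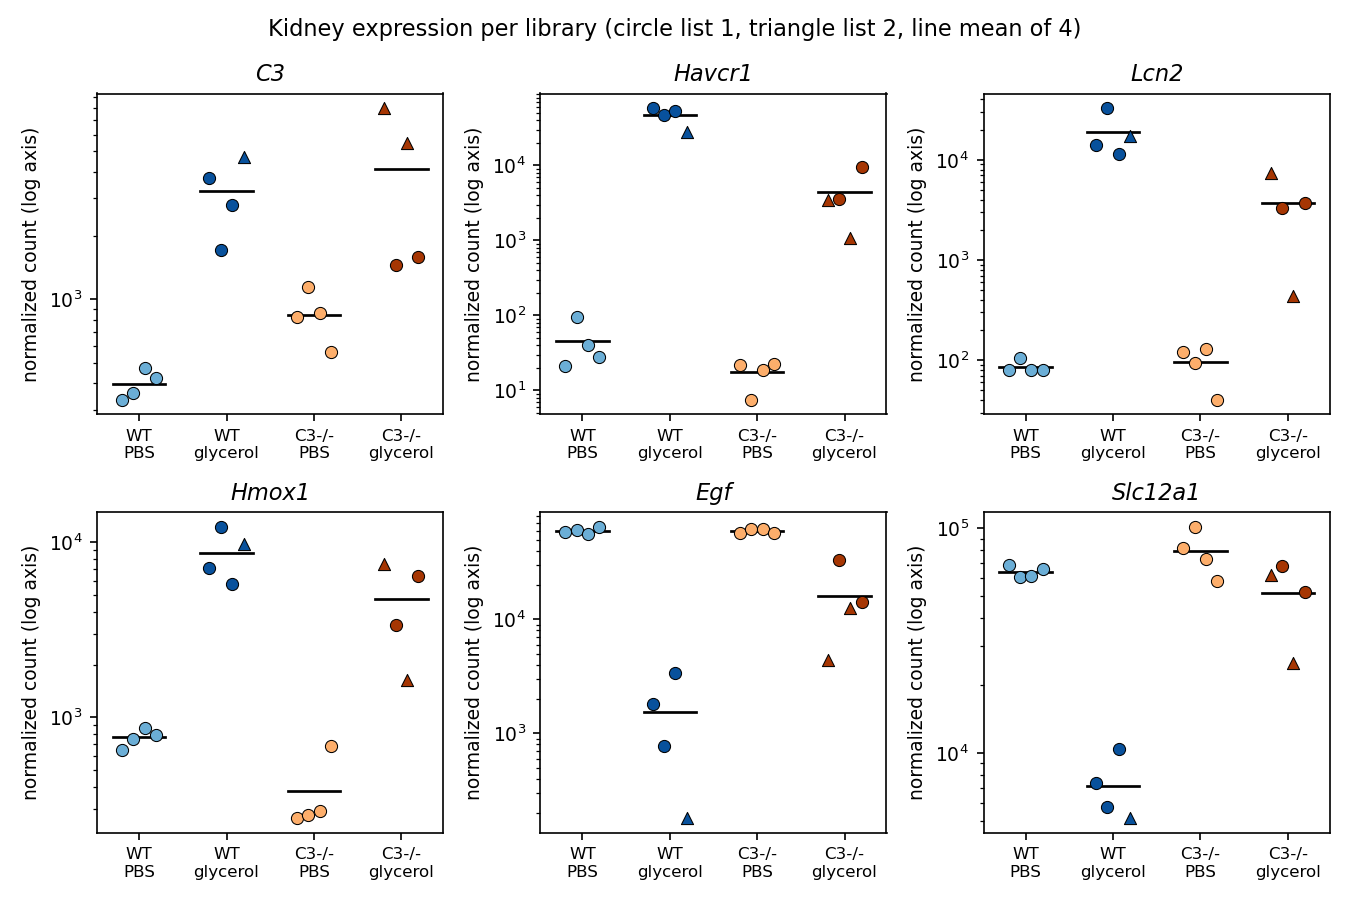
Normalized counts of C3, Havcr1, Lcn2, Hmox1, Egf and Slc12a1 on log axes, 1 point per library (circles list 1, triangles list 2), with a line at the mean of 4. Havcr1 averaged 46250 in WT glycerol and 4394 in libraries labelled C3-/- after glycerol, and Egf 1537 and 16090.

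The comparison of glycerol with PBS in WT kidney asked which transcripts change in rhabdomyolysis-associated acute kidney injury. Genes of tubule injury, heme handling, cytokines and amino acid stress rose, and genes of tubular transport and fatty acid oxidation fell. Havcr1, which encodes the tubule injury marker KIM-1 (ENSMUSG00000040405; chromosome 11, 46735080 to 46779578), went from 46.04 ± 33.2 to 46250 ± 13050 (SD, n = 4 each), a log2 fold change of 10.12 ± 0.57 (adjusted p = 1.8e-07). Lcn2, which encodes the iron-siderophore carrier NGAL (chromosome 2, 32384633 to 32388252), rose by 7.66 ± 0.65 (adjusted p = 3.4e-06). Other large rises were those of Krt20, an epithelial keratin (8.97 ± 1.06), Timp1, a metalloproteinase inhibitor (8.38 ± 0.73), Fosl1, an AP-1 subunit (8.17 ± 1.24), and Gsta1, a glutathione transferase (8.03 ± 0.47). Egf, the growth factor made by the distal nephron (chromosome 3, 129677565 to 129755316), fell from 60130 ± 3958 to 1537 ± 1409, a log2 fold change of -5.96 ± 0.7 (adjusted p = 4.3e-05). Nccrp1 (-5.82 ± 0.42), the potassium channel gene Kcnt1 (-5.18 ± 0.54) and Car3, a carbonic anhydrase gene (-4.73 ± 0.75), fell as well. The acute-phase gene Saa1 was listed at 0 in every WT PBS library and averaged 202.3 ± 103 (n = 4) after glycerol.

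Of the 21 tubule injury genes tested, 19 rose in WT and the other 2 were not called, 21 rose when adjusted over the list alone, and the median log2 fold change was 3.52. Sox9, a transcription factor of regenerating tubule cells, rose by 6.42 ± 0.43, and Lgals3, which encodes galectin-3, by 3.52 ± 0.25. The list stood above other genes in limma's camera test (adjusted p = 1.91e-19), with adjusted p = 0.0594 with an estimated correlation. In the heme and Nrf2 response list 14 of 20 genes rose (15 rose and 1 fell adjusted over the list alone), with a median of 1.45 (adjusted p = 1.24e-09; adjusted p = 0.0584 with an estimated correlation). Hmox1, the heme oxygenase that degrades heme (chromosome 8, 75093621 to 75100589), rose from 766.7 ± 90.98 to 8754 ± 2893 (n = 4), a log2 fold change of 3.46 ± 0.43. The metallothionein gene Mt2 rose by 5.66 ± 0.59 and the biliverdin reductase gene Blvrb by 2.85 ± 0.36. Of 18 genes of the unfolded protein and amino acid stress response 12 rose (13 rose and 2 fell adjusted over the list alone; median 1.39, adjusted p = 4.46e-07; adjusted p = 0.105 with an estimated correlation). Trib3, a pseudokinase gene induced by ATF4, rose by 4.79 ± 0.23 and Asns, asparagine synthetase, by 3.14 ± 0.38.

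Among 24 cytokine and chemokine genes 21 rose in WT (21 adjusted over the list alone; median 2.33, adjusted p = 5.02e-16; adjusted p = 0.0501 with an estimated correlation). The neutrophil chemokine gene Cxcl1 rose by 5.06 ± 0.49, the monocyte chemokine gene Ccl2 by 3.92 ± 0.49, Il6 by 5.47 ± 0.61 and Lif, a cytokine of the interleukin-6 family, by 6.24 ± 0.42. Of the 21 genes of the NF-kB and immediate early response 14 rose (14 adjusted over the list alone; median 1.53, adjusted p = 2.97e-09; adjusted p = 0.061 with an estimated correlation), including Socs3, a feedback inhibitor of cytokine signalling, by 5.3 ± 0.44. Of 10 neutrophil genes 7 rose (7 adjusted over the list alone; median 1.88, adjusted p = 0.000726; adjusted p = 0.141 with an estimated correlation). Of the macrophage and dendritic cell genes 3 rose and 3 fell among 18 (3 and 3 adjusted over the list alone). The lysosomal Cd68 rose by 2.87 ± 0.37, and the receptor gene Csf1r and the antigen-presentation gene Cd74 had changes of -0.92 ± 0.23 and -0.83 ± 0.19. That list did not differ from other genes (adjusted p = 0.445). The matrix and fibroblast list had 8 genes that rose and 2 that fell among 19 (10 and 2 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.0004; adjusted p = 0.278 with an estimated correlation). Its matrix glycoprotein gene Tnc rose by 2.5 ± 0.41.

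Complement genes moved in both directions in WT. Of 15 component genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.542). C1qb, a chain of C1q, rose by 1.14 ± 0.3 (adjusted p = 0.011), and C8a, a membrane attack complex subunit, fell by 2.75 ± 0.57 (adjusted p = 0.0029). Hc, which encodes C5, rose by 3.51 ± 1.08 (adjusted p = 0.026), a call that ended without WT PBS replicates 1, 2 or 3 (0.082, 0.065 and 0.081) or WT glycerol replicate 2 (0.08). The alternative pathway gene Cfb did not pass (-0.52 ± 0.55, adjusted p = 0.51; -0.95 with adjusted p = 0.0086 within list 1). Of 18 receptor and regulator genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; median 0.05, camera adjusted p = 0.542). The C5a receptor gene C5ar1 rose by 2.23 ± 0.37 and the terminal-pathway regulator Clu by 3.43 ± 0.59, while the complement receptor gene Cr2 fell by 2.39 ± 0.43.

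Transport genes of the nephron fell together in WT. Of 26 proximal tubule genes 16 fell (18 adjusted over the list alone; median -1.7, adjusted p = 4.06e-07; adjusted p = 0.195 with an estimated correlation). The phosphate transporter gene Slc34a1 fell by 2.8 ± 0.59, from 106300 ± 10180 to 17790 ± 8864 (n = 4), its relative Slc34a3 by 3.17 ± 0.39 and the amino acid transporter gene Slc6a19 by 2.44 ± 0.33. Of 22 fatty acid oxidation genes 11 fell (17 adjusted over the list alone; median -1.21, adjusted p = 6.18e-06; adjusted p = 0.0945 with an estimated correlation), among them Ppargc1a, a coactivator of mitochondrial genes, by 2.05 ± 0.3. In the list of the loop of Henle and distal tubule 10 of 16 genes fell (10 adjusted over the list alone; median -1.51, adjusted p = 7.75e-06; adjusted p = 0.105 with an estimated correlation). Slc12a1, the cotransporter blocked by loop diuretics (chromosome 2, 125152505 to 125230002), fell by 3.22 ± 0.31. Umod, which encodes uromodulin, was 146200 ± 7992 in PBS and 89150 ± 47070 in glycerol libraries (adjusted p = 0.18). Of 15 collecting duct genes 7 fell (8 adjusted over the list alone; median -0.81, adjusted p = 0.000702; adjusted p = 0.105 with an estimated correlation), including the water channel gene Aqp3 by 2 ± 0.31. The podocyte gene Nphs1 did not differ detectably (-0.1 ± 0.19, adjusted p = 0.72).

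In all, limma called 2262 genes higher and 2404 lower after glycerol in WT among 18035 tested, and in 7323 genes (40.6%) the values of the groups did not overlap, against 2.9% by chance. Within list 1, where 3 glycerol libraries remained, 10028 genes were called, with 4647 of the pooled calls among them in the same direction. With adjustment for list and Y-linked transcripts 8886 were called, including all 4666. The 60 genes called and examined by name in this comparison kept their direction and call within list 1 (largest adjusted p = 0.014), where the medians were 3.68 for tubule injury, 2.05 for cytokines and -1.67 for proximal tubule transport.

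The same comparison in libraries labelled C3-/- asked which changes follow glycerol when C3 is targeted. Heme handling, amino acid stress and cytokine genes rose here too. Tubule injury genes rose in part in the pooled fit, with 8 of 21 called. Within list 1, 18 of the 21 were called higher, and 19 with adjustment for list and Y-linked transcripts. The pooled list call was lost with an estimated correlation (camera adjusted p = 0.219). Havcr1 went from 17.62 ± 6.931 to 4394 ± 3565 (n = 4 each), a log2 fold change of 7.6 ± 0.57 (limma adjusted p = 5.1e-06; 8.39 within list 1). Lcn2 went from 95.96 ± 39.86 to 3718 ± 2855, a change of 4.82 ± 0.65 (adjusted p = 0.00061). Other large rises were those of Fosl1 (7.61 ± 1.24), Ptprn, a receptor-type phosphatase gene of secretory granules (7.18 ± 0.6), Gsta1 (7.1 ± 0.47), Cyp2a5, a cytochrome P450 gene (6.28 ± 0.87; 4.7 within list 1), and Derl3, a component of endoplasmic reticulum protein degradation (5.81 ± 0.68). The lactate transporter gene Slc5a12 fell by 4.09 ± 0.71 (adjusted p = 0.0036; -2.59 within list 1), and Clec2h and Cyp2d26 by 3.54 ± 0.33 and 2.96 ± 0.28.

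Of the 21 tubule injury genes 8 rose in libraries labelled C3-/- (11 adjusted over the list alone; median 1.54, adjusted p = 9.8e-10; adjusted p = 0.219 with an estimated correlation). In the heme and Nrf2 response 12 of 20 rose (12 adjusted over the list alone; median 1.21, adjusted p = 2.43e-11, and 0.0449 with an estimated correlation). Hmox1 rose by 3.53 ± 0.43, Srxn1, which repairs peroxiredoxins, by 3.02 ± 0.37, Blvrb by 3.7 ± 0.36 and Nqo1, a quinone reductase, by 1.55 ± 0.21. Of 18 genes of the unfolded protein and amino acid stress response 10 rose (13 adjusted over the list alone; median 1.45, adjusted p = 6.87e-13, and 0.0449 with an estimated correlation). Trib3 stood at 5.63 ± 0.23 (adjusted p = 3.7e-09), the glutathione-degrading Chac1 at 4.22 ± 0.51 and Asns at 3.12 ± 0.38. Of 17 p53 target and senescence genes 6 rose (8 rose and 1 fell adjusted over the list alone; median 0.67, adjusted p = 4.98e-05, and 0.0449 with an estimated correlation). The p53 median was 0.35 among genes with a mean of at least 100 and 0.4 without C3-/- PBS replicate 4, with the call kept. The cell cycle inhibitor gene Cdkn1a rose by 3.11 ± 0.4 and Gdf15, a stress cytokine, by 3.6 ± 0.43. Among the 24 cytokine and chemokine genes 11 rose (16 adjusted over the list alone; median 1.54, adjusted p = 6.87e-13, and 0.0449 with an estimated correlation). With a pseudocount of 8 the cytokine median was 0.9, with the call kept. Cxcl1 rose by 5.54 ± 0.49 and the interferon-induced chemokine gene Cxcl10 by 2.29 ± 0.29. The NF-kB and immediate early list had 10 of 21 genes that rose (14 adjusted over the list alone; median 1.29, adjusted p = 7.09e-11, and 0.0449 with an estimated correlation), with Atf3 at 5.2 ± 0.51 and Myc at 3.02 ± 0.29.

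Transport genes fell here as well, fewer of them past the threshold. Of 26 proximal tubule genes 5 fell (9 adjusted over the list alone; median -0.91, adjusted p = 1.32e-05; adjusted p = 0.375 with an estimated correlation), including Slc6a19 by 2.49 ± 0.33. Within list 1, 10 of the 26 proximal tubule genes fell, and 14 with adjustment for list and Y-linked transcripts. Slc34a1 was 93230 ± 28960 after PBS and 56980 ± 67700 after glycerol (adjusted p = 0.2). Of 22 fatty acid oxidation genes 3 fell (6 adjusted over the list alone; median -0.85, adjusted p = 0.000552; adjusted p = 0.219 with an estimated correlation), among them the thiolase gene Acaa2 by 1.4 ± 0.24. The median of that list was -0.4 within list 1 and -0.49 with adjustment for list and Y-linked transcripts, with the call kept in both (adjusted p = 0.000436 and 3.45e-06). Egf was 59610 ± 2886 after PBS and 16090 ± 12260 after glycerol (-2.23 ± 0.7, adjusted p = 0.076; -1.46 with adjusted p = 0.033 within list 1). In the loop of Henle and distal tubule list the calcium-binding protein gene Calb1 was the 1 member of 16 called, with a change of -1.37 ± 0.26 (3 fell adjusted over the list alone). The median of the list was -0.58 (adjusted p = 0.00871; adjusted p = 0.375 with an estimated correlation). That camera call ended within list 1 (median -0.36, adjusted p = 0.122) and with adjustment for list and Y-linked transcripts (-0.19, adjusted p = 0.242). It also ended with array weights (-0.27, adjusted p = 0.254), with the term for list alone (-0.28, adjusted p = 0.0724) and without C3-/- glycerol replicate 4 (adjusted p = 0.051). The median was larger in size, -0.92, in libraries with Y-linked transcripts only, a fit with 1 C3-/- PBS library.

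limma called 663 genes higher and 353 lower after glycerol in libraries labelled C3-/-, and 3470 genes (19.2%) had groups that did not overlap, against 2.9% by chance. In list 1 (2 glycerol libraries) 4142 genes were called, 962 of them pooled calls in the same direction, and with adjustment for list and Y-linked transcripts 3393 were called, 985 of them pooled calls. A fit of these 8 libraries alone called 308 genes and ended 10 of the 50 calls among genes examined by name, that for C3 included (1.95, adjusted p = 0.12). The libraries with Y-linked transcripts alone, with 1 C3-/- PBS library, called 7. In this last fit 47 of the 50 calls among genes examined by name ended, those for Havcr1, Lcn2, Hmox1 and Slc6a19 included (adjusted p = 0.11, 0.3, 0.73 and 0.3; log2 changes of 7.09, 4.95, 2.23 and -2.13), and those for Trib3, Gsta1 and Ptprn held, with a tubule injury median of 1. The 50 genes called and examined by name kept their direction and call within list 1 (largest adjusted p = 0.043), where the list medians were 1.66 for tubule injury, 1.15 for heme and Nrf2, 1.4 for cytokines and -0.92 for proximal tubule transport.

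Of the genes called in the 2 glycerol comparisons, 585 were higher in both and 291 lower in both, against 83.2 and 47.1 for independent lists, and none went in opposite directions (limma; 6844 and 4457 genes had an unadjusted p below 0.05). Across the 18035 genes the 2 sets of log2 fold changes correlated with Pearson's r = 0.7 (0.67 within list 1), where genes are not independent replicates. The 2 comparisons share no libraries.

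**Figure D3:**
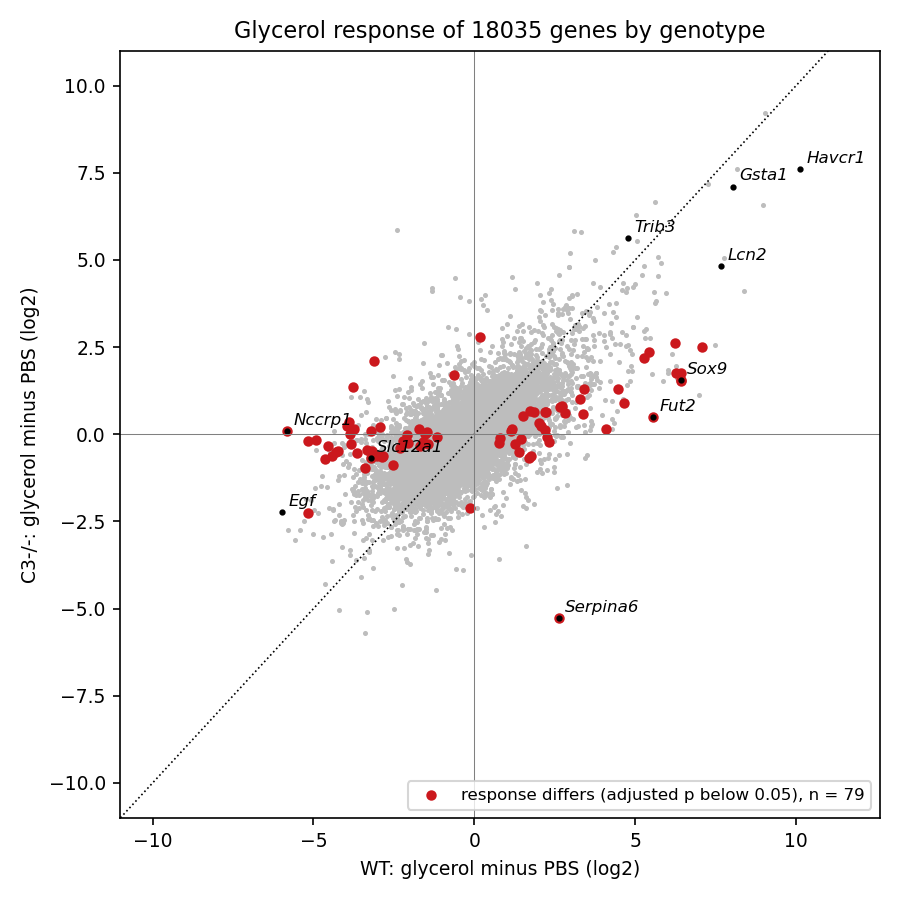
Log2 fold change after glycerol of 18035 genes in libraries labelled C3-/- (vertical) against WT (horizontal), 1 point per gene, with a dotted line of equal response. Red points are the 79 genes whose responses differed, such as Sox9, with a log2 change of 6.42 in WT and a difference between the responses of -4.86.

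Kidneys labelled C3-/- and WT were next compared after glycerol. By list medians tubule injury, cytokine, matrix and neutrophil transcripts were lower in the libraries labelled C3-/-. Those of the loop of Henle and distal tubule and of the collecting duct were higher, with part of the members called. Of these list calls the cytokine call alone held with an estimated correlation. Havcr1 was lower by a log2 difference of -3.73 ± 0.57 (adjusted p = 0.00071; -3.16 within list 1), Sox9 by -4.48 ± 0.43 (adjusted p = 1.1e-05), Timp1 by -4.17 ± 0.73 and Lcn2 by -2.79 ± 0.65. Fut2, a fucosyltransferase gene, averaged 214.9 ± 38.3 in WT and 2.872 ± 1.21 in libraries labelled C3-/- (-5.84 ± 0.44). Slc12a1 was higher by 2.82 ± 0.31 (adjusted p = 3.5e-05; 2.97 within list 1), Nccrp1 by 6.77 ± 0.42, Kcnt1 by 5.61 ± 0.54 and the tissue kallikrein gene Klk1b22 by 7.51 ± 0.59.

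Of the 21 tubule injury genes 14 were lower in libraries labelled C3-/- (19 adjusted over the list alone; median -2.05, adjusted p = 3.2e-15; adjusted p = 0.0638 with an estimated correlation). Anxa2, a membrane-binding annexin gene, was at -2.05 ± 0.28 and the keratin gene Krt8 at -1.17 ± 0.19. The mean log2 value of the list was 12.56 ± 0.3 (SD, n = 4) in WT glycerol and 10.34 ± 1.08 (n = 4) in libraries labelled C3-/-. All 4 WT values lay above all 4 others (exact permutation p = 0.029, two-sided, the smallest that 4 against 4 can give). Of 24 cytokine and chemokine genes 14 were lower (16 adjusted over the list alone; median -1.67, adjusted p = 2.74e-14, and 0.038 with an estimated correlation). Ccl2 differed by -3.67 ± 0.49, Ccl12 by -3.29 ± 0.43, Lif by -3.31 ± 0.42, Cxcl5 by -4.89 ± 0.51 and Il6 by -3.34 ± 0.61. Of 23 interferon response genes 4 were lower (8 adjusted over the list alone; median -0.52, adjusted p = 1.64e-05, and 0.038 with an estimated correlation). The matrix and fibroblast list had 12 of 19 genes lower (16 adjusted over the list alone; median -1.51, adjusted p = 3.16e-13; adjusted p = 0.0638 with an estimated correlation). Its collagen gene Col3a1 was at -2.93 ± 0.39, the cross-linking enzyme gene Lox at -2.89 ± 0.35 and Fn1, fibronectin, at -1.91 ± 0.24. Of 10 neutrophil genes 8 were lower (8 adjusted over the list alone; median -2.8, adjusted p = 4.63e-07; adjusted p = 0.0638 with an estimated correlation), among them S100a8 at -3.5 ± 0.61 and Clec4d at -3.8 ± 0.57. With a pseudocount of 8 the neutrophil median was -1.78, with the call kept. The interferon median was -0.86 with the Y-linked term without list 2, with the call kept. The cytokine, matrix and neutrophil lists had medians of -0.68, -0.71 and -1.7 after PBS (adjusted p = 0.123, 0.129 and 0.0374 with an estimated correlation, where the call of the neutrophil list alone held).

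Receptors and regulators of complement were lower in libraries labelled C3-/- after glycerol in 5 of 18 cases and higher in 1 (10 and 1 adjusted over the list alone; median -0.65, adjusted p = 0.000297; adjusted p = 0.0638 with an estimated correlation). C5ar1 differed by -2.12 ± 0.37, its relative C5ar2 by -3.33 ± 0.54, Itgam, a chain of complement receptor 3, by -2.97 ± 0.54 and Clu by -3.41 ± 0.59. The C3a receptor gene C3ar1 had 65.78 ± 23.4 in WT and 70.05 ± 74.8 in libraries labelled C3-/- (n = 4 each, adjusted p = 0.73). Among 15 component genes 2 were lower and 1 higher (2 and 1 adjusted over the list alone; median -0.44, adjusted p = 0.0632): C7 at -1.46 ± 0.3, Masp1 at -1.28 ± 0.3 and C8a at 3.38 ± 0.57. The component list passed within list 1 (7 lower and 1 higher, median -0.67, adjusted p = 0.00942) and with adjustment for list and Y-linked transcripts (median -0.65, adjusted p = 0.0132). Macrophage and dendritic cell genes were lower in 3 of 18 cases and higher in 1 (4 and 1 adjusted over the list alone; median -0.55, adjusted p = 0.00578; adjusted p = 0.355 with an estimated correlation). That call ended without WT glycerol replicate 4 (adjusted p = 0.0617), without C3-/- glycerol replicate 4 (0.0788) and among genes with a mean of at least 100 (0.0508). The median was -1 without C3-/- glycerol replicate 1, -0.32 without C3-/- glycerol replicate 3, -0.82 within list 1, where 12 genes were lower, and -0.87 with adjustment for list and Y-linked transcripts.

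In the loop of Henle and distal tubule list 6 of 16 genes were higher in libraries labelled C3-/- (8 higher and 1 lower adjusted over the list alone; median 0.76, adjusted p = 5e-05; adjusted p = 0.108 with an estimated correlation). Pvalb, parvalbumin of the distal tubule, was higher by 4.42 ± 0.57 and Egf by 3.72 ± 0.7. Of 15 collecting duct genes 6 were higher (8 adjusted over the list alone; median 0.81, adjusted p = 1.64e-05; adjusted p = 0.0638 with an estimated correlation), with the anion exchanger gene Slc4a1 at 2.64 ± 0.44 and Aqp3 at 1.4 ± 0.31. The proximal tubule list had a median of 0.69 (adjusted p = 0.031; adjusted p = 0.584 with an estimated correlation). That camera call ended without WT glycerol replicate 2 (median 0.31, adjusted p = 0.592), C3-/- glycerol replicate 3 (0.34, adjusted p = 0.256) or C3-/- glycerol replicate 4 (0.62, adjusted p = 0.101). It also ended with array weights (0.35, adjusted p = 0.263) and with the term for list alone (0.55, adjusted p = 0.0889). With the term for Y-linked transcripts the median was 1.14 and the call was kept. The heme and Nrf2 response list did not pass (median -0.2, adjusted p = 0.0712), and limma called none of its 20 genes, with 6 lower at an unadjusted p below 0.05. With adjustment for list and Y-linked transcripts 4 of its genes were lower and the list passed (median -0.2, adjusted p = 0.0359). Hmox1 was 8754 ± 2893 in WT and 4740 ± 2729 in libraries labelled C3-/- (adjusted p = 0.13). Trib3 was higher, by 1.52 ± 0.23 (adjusted p = 0.00068).

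After glycerol limma called 1150 genes higher and 875 lower in libraries labelled C3-/-, and 2035 genes (11.3%) had groups that did not overlap, against 2.9% by chance. Within list 1, with 3 WT and 2 C3-/- libraries, 5432 genes were called, 1825 of them pooled calls in the same direction, and 6068 with adjustment for list and Y-linked transcripts, 1979 of them pooled calls. A fit of these 8 libraries alone called 297 genes and ended 18 of the 55 calls among genes examined by name, including those for Lcn2, Egf, Il6, Clu, Itgam, Krt8, C7, C8a, Masp1, Slc4a1 and Aqp3 (adjusted p = 0.14, 0.089, 0.053, 0.072, 0.077, 0.083, 0.079, 0.069, 0.16, 0.06 and 0.13), with log2 differences as in the pooled fit. The libraries with Y-linked transcripts alone ended 6 of the 55, including those for Aqp3, C7, Krt8 and Masp1 (adjusted p = 0.13, 0.08, 0.052 and 0.053; log2 differences of 1.31, -1.29, -1.17 and -1.58), with a median of 0.49 for the loop of Henle and distal tubule. With array weights the tubule injury median was -1.32. All 55 kept direction and call within list 1 (largest adjusted p = 0.025). List 1 medians were -1.52 for tubule injury, -1.84 for cytokines, -1.42 for matrix, -2.14 for neutrophil, 1.06 for the loop of Henle and distal tubule and 0.52 for the collecting duct.

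**Figure D4:**
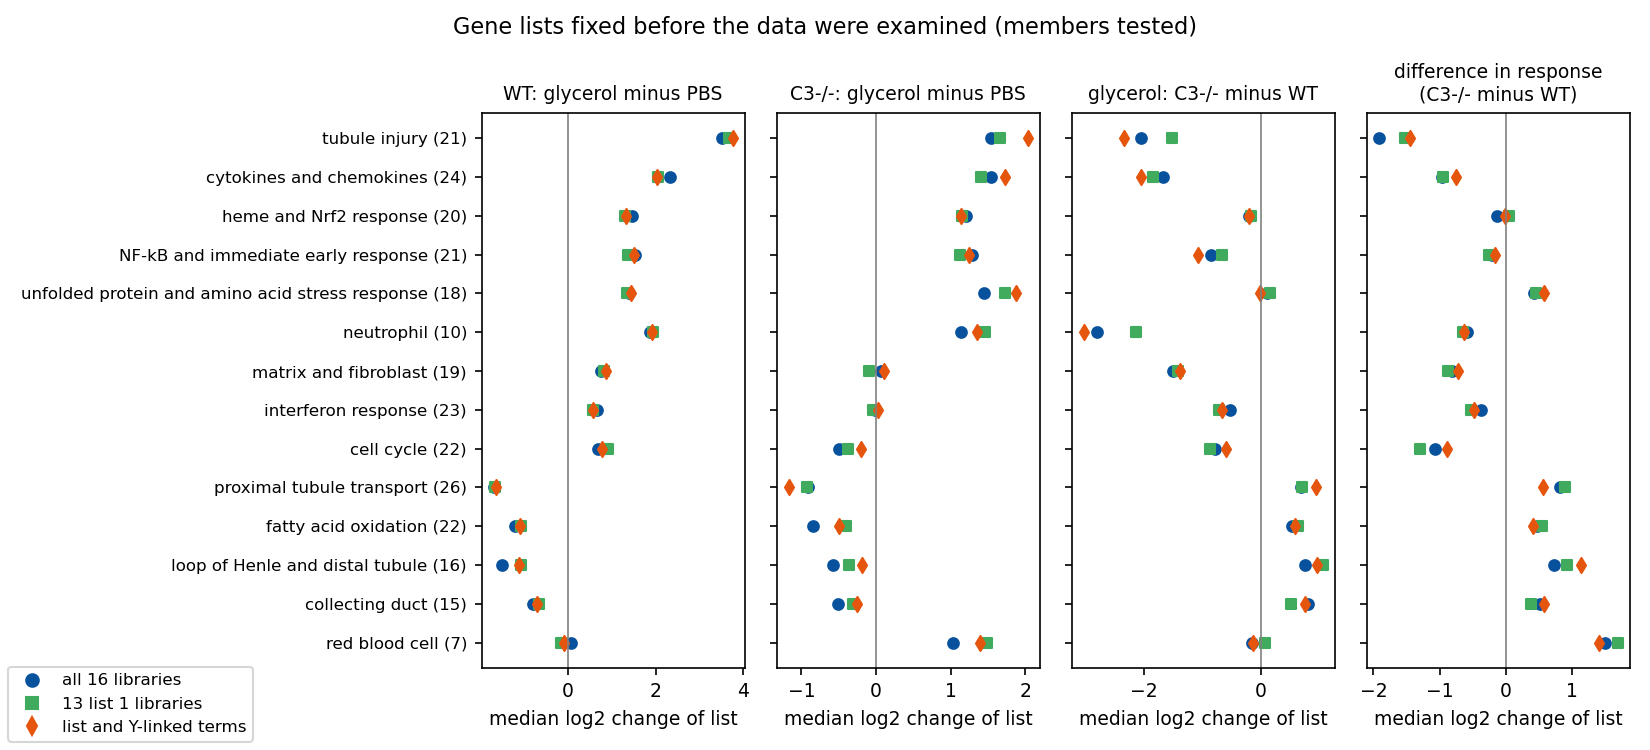
Median log2 change of the members of 14 lists in 4 comparisons, with the number tested in brackets and 1 marker per fit: all 16 libraries (circles), 13 list 1 libraries (squares), and all libraries with terms for list and Y-linked transcripts (diamonds); the axes of the panels differ. Tubule injury rose by a median of 3.52 in WT and 1.54 in libraries labelled C3-/-, and the difference in response was -1.92.

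Without glycerol, single genes differed between the 2 genotypes by large amounts. Ugt2b38, a glucuronosyltransferase gene (chromosome 5, 87409942 to 87424203), averaged 30100 ± 4614 in WT PBS and 5.447 ± 5.229 in C3-/- PBS (n = 4 each), a log2 difference of -12.54 ± 0.65 (limma adjusted p = 2.3e-08). Gvin1, an interferon-inducible GTPase gene, averaged 1096 ± 169.5 in WT and 3.177 ± 6.355 in C3-/- PBS (adjusted p = 6.4e-07), and Trim12a, Serpina1d and Chd9 were lower by -7.96 ± 0.6, -7.77 ± 0.53 and -7.48 ± 0.33. Chd9, a chromatin remodelling gene (chromosome 8, 90828352 to 91054516), had 48710 ± 10950 in WT and 267.7 ± 26.06 in C3-/- PBS. Higher in libraries labelled C3-/- were Serpina6, which encodes corticosteroid-binding globulin (10.16 ± 1.09), Klk1b22 (5.99 ± 0.59), Ifi44l (5.53 ± 0.37), the calcium channel subunit gene Cacna2d2 (4.16 ± 0.56) and Gdpd3, a lysophospholipase D gene (3.58 ± 0.44). Ugt2b38, Serpina1d, Klk1b22 and Gvin1 belong to families of similar genes, and how shared reads were assigned is not given in the sources used here. The 3 libraries without Y-linked transcripts after PBS were all labelled C3-/-.

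Complement receptor and regulator genes were lower in C3-/- PBS in 3 of 18 cases (9 adjusted over the list alone; median -0.68, adjusted p = 6.79e-07, and 0.0187 with an estimated correlation). C5ar2 differed by -2.84 ± 0.54. The component gene C7 differed by -2.81 ± 0.3 (adjusted p = 4.9e-05) and was the 1 component gene of 15 called (1 adjusted over the list alone; median -0.55, adjusted p = 0.000548; adjusted p = 0.123 with an estimated correlation). Of 10 neutrophil genes 2 were lower (6 adjusted over the list alone; median -1.7, adjusted p = 6.29e-08, and 0.0374 with an estimated correlation), with S100a8 at -3.16 ± 0.61 (adjusted p = 0.011). Lists of other blood and immune cells were lower alongside the complement receptor and neutrophil genes. The red blood cell list had a median of -1.5 (camera adjusted p = 6.29e-08, and 0.0187 with an estimated correlation) and the lymphocyte list of -0.61 (adjusted p = 6.17e-06, and 0.0187 with an estimated correlation). The lymphocyte median was -1.06 with the Y-linked term without list 2, with the call kept. The macrophage and dendritic cell list had a median of -0.68 (adjusted p = 1.88e-06; adjusted p = 0.123 with an estimated correlation). limma called none of its 18 genes (5 lower adjusted over the list alone; 6 lower and 1 higher at an unadjusted p below 0.05), and within list 1 it called 12 lower and 1 higher. Cytokine and chemokine genes were lower in 4 of 24 cases (5 adjusted over the list alone; median -0.68, adjusted p = 1.23e-06; adjusted p = 0.123 with an estimated correlation), including Cxcl1 at -2.92 ± 0.49 (adjusted p = 0.0035). Of 19 matrix and fibroblast genes 2 were lower (7 adjusted over the list alone; median -0.71, adjusted p = 7.91e-08; adjusted p = 0.129 with an estimated correlation). With a pseudocount of 8 the neutrophil and cytokine medians were -0.62 and -0.4, with the calls kept. limma called none of the 21 tubule injury genes, with 1 lower at an unadjusted p below 0.05 (median 0.05, camera adjusted p = 0.924), and Havcr1 did not pass (-1.21 ± 0.57, adjusted p = 0.49). With adjustment for list and Y-linked transcripts the tubule injury list was lower in C3-/- PBS (median -0.51, adjusted p = 0.00116), with 1 of its genes called.

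After PBS limma called 187 genes higher and 215 lower in libraries labelled C3-/-, and 4873 genes (27%) had groups that did not overlap, against 2.9% by chance. A fit of these 8 libraries alone called 4579 genes with the same log2 differences, so only the estimate of spread changed. Of the 402 pooled calls 136 were also higher and 127 also lower after glycerol, against 11.9 and 10.4 for independent lists, and 4 and 2 went the opposite way; the comparisons share no libraries. Within list 1 the fit called 3481 genes and included all 402. All PBS libraries were in list 1, so the log2 differences there are those of the pooled fit and only the spread changed. With adjustment for list and Y-linked transcripts 628 were called, of which 293 were shared. With the term for Y-linked transcripts alone 157 were called and 12 of the 33 calls among genes examined by name ended. Among libraries with Y-linked transcripts, where 1 C3-/- PBS library remained, 51 were called. That fit ended 25 of the 33, including those for C7, C5ar2, Cxcl1, S100a8, Klk1b22, Gdpd3 and Cacna2d2 (adjusted p = 0.094, 0.098, 0.14, 0.13, 0.14, 0.17 and 0.23). Their log2 differences there were -2.52, -3.88, -3.14, -4.51, 5.77, 3.12 and 4.19. The calls for Ugt2b38, Gvin1, Chd9 and Serpina6 held, with a median of -0.28 for the complement components.

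The last comparison asked whether the response to glycerol itself differed between the genotypes. By list medians the rise of tubule injury and cytokine genes, and the fall of some distal nephron genes, was smaller in libraries labelled C3-/-. Few members of these lists were called, and the list calls did not hold with an estimated correlation. Sox9 (chromosome 11, 112782224 to 112787760) went from 13.82 ± 4.401 to 1381 ± 860.3 in WT and from 18.72 ± 7.566 to 58.57 ± 26.08 in libraries labelled C3-/- (n = 4 each), a difference between the log2 responses of -4.86 ± 0.61 (limma adjusted p = 0.0029). Fut2 differed by -5.06 ± 0.62 (adjusted p = 0.0027), Lif by -3.62 ± 0.59 (adjusted p = 0.012) and Serpina10, which encodes the protein Z-dependent protease inhibitor, by -3.1 ± 0.48 (adjusted p = 0.011). The chemokine gene Cxcl5 was listed at 0 in all 8 PBS libraries and averaged 86.49 ± 19.3 in WT glycerol and 2.624 ± 2.55 in C3-/- glycerol libraries (adjusted p = 0.0098). Nccrp1 went from 1232 ± 239.9 to 22.39 ± 10.11 in WT and from 2317 ± 826.1 to 2680 ± 1542 in libraries labelled C3-/-, a difference of 5.91 ± 0.59 (adjusted p = 0.00098). Ppp1r1b, a regulator of protein phosphatase 1, differed by 3.54 ± 0.4, Wfdc15b, of the whey acidic protein family, by 2.91 ± 0.42, Kcnt1 by 4.99 ± 0.76 and Slc12a1 by 2.55 ± 0.43 (adjusted p = 0.015; 0.066 after quantile normalization).

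Of the 21 tubule injury genes 3 had a smaller response (14 adjusted over the list alone), and the list as a whole differed by a median of -1.92 (camera adjusted p = 8.7e-20; adjusted p = 0.0565 with an estimated correlation). Within list 1 the median difference was -1.53 (camera adjusted p = 1.57e-13), and with adjustment for list and Y-linked transcripts -1.44 (adjusted p = 3.82e-12). Both p-values used the preset correlation, and no estimated correlation was tried in these fits. Havcr1, Lcn2 and Timp1 were not called on their own (-2.52 ± 0.81, -2.84 ± 0.92 and -4.26 ± 1.03, adjusted p = 0.215, 0.22 and 0.087; 0.108, 0.028 and 0.0066 within list 1). The cytokine and chemokine list differed by -0.97 (3 of 24 genes, 8 adjusted over the list alone; adjusted p = 2.01e-07; adjusted p = 0.0859 with an estimated correlation; -0.95 within list 1, and -0.33 among genes with a mean of at least 100). The matrix and fibroblast list differed by -0.82, with none of its 19 genes called by limma (6 lower adjusted over the list alone; 7 lower and 1 higher at an unadjusted p below 0.05; adjusted p = 1.64e-06; adjusted p = 0.208 with an estimated correlation). The neutrophil list did not pass (median -0.58, adjusted p = 0.0629). In the cell cycle list limma called none of 22 genes, with 12 lower at an unadjusted p below 0.05 and 1 adjusted over the list alone. The list differed by a median of -1.07 (adjusted p = 1.66e-10; adjusted p = 0.0538 with an estimated correlation; -1.29 within list 1). Its topoisomerase gene Top2a had a difference of -1.95 ± 0.48 (adjusted p = 0.094). The loop of Henle and distal tubule list differed by 0.72 (1 of 16 genes, 5 adjusted over the list alone; adjusted p = 4.05e-05; adjusted p = 0.133 with an estimated correlation; 0.92 within list 1 and 1.13 with adjustment for list and Y-linked transcripts). No member of the heme and Nrf2 response was called by limma (2 lower at an unadjusted p below 0.05 among 20), and the list did not differ (median -0.13, adjusted p = 0.205).

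limma called 40 genes with a more positive and 39 with a more negative response in libraries labelled C3-/-. Within list 1 it called 1858 and with adjustment for list and Y-linked transcripts 1580, each including all 79. In the libraries with Y-linked transcripts alone, where 1 C3-/- PBS library remained, the tubule injury list differed by a median of -1.73. The loop of Henle and distal tubule list differed there by 0.39. The 20 genes called and examined by name kept direction and call within list 1 (largest adjusted p = 0.018). With the term for Y-linked transcripts alone 3 of the 20 calls ended (Chil3, Fgg and Vmn1r18 at -3.85, -4.35 and 4.1, adjusted p = 0.052, 0.059 and 0.052), and none was called in the libraries with Y-linked transcripts alone.

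The authors' deposited table for WT listed 3247 genes higher and 2687 lower after glycerol at an adjusted p below 0.05, their table for C3-/- 2085 and 1096, and their table of the genotypes after glycerol 1956 higher and 1483 lower in C3-/-. Log2 fold changes in the authors' deposited tables correlated across genes with those of limma with Pearson's r = 0.94, 0.93 and 0.93, where genes are not independent replicates. Of the limma calls, 4562 of 4666, 1016 of 1016 and 2003 of 2025 were past the threshold with the same sign in the authors' deposited tables.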

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

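The tests of the smaller response, of the genotype differences after PBS, of stronger injury in list 2 and of list 2 effects on gene lists were chosen after the results were seen, as were all fits with a term for Y-linked transcripts. The tests of the authors' scaling, of gene length and GC content, and of other splits of the libraries were fixed before.

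Among 64 groups of 4 values examined, 10 held 1 library far from the other 3, against 3.2 by chance at about 1 in 20. WT glycerol replicate 4, of list 2, stood out in Chd9 (355000, the others 101000 to 125000), in the total (38.4 M, the others 26.7 to 28.6) and in genes listed at 0 (3370, the others 190 to 539). C3-/- PBS replicate 4, the 1 library of its group with Y-linked transcripts, stood out in Hmox1 (688, the others 264 to 291) and in the total (34 M, the others 28.6 to 29.3). C3-/- glycerol replicate 3 had a tubule injury score of 8.73 (the others 10.8 to 11), which lay within the 8.09 to 8.8 of the C3-/- PBS libraries. C3-/- glycerol replicate 1 had a Timp1 value of 550 (the others 27.9 to 94.3). The remaining 3 were Gvin1 in C3-/- PBS replicate 1 (12.7, the others 0), Lcn2 in WT PBS replicate 2 (105, the others 78.9 to 79.3) and the total of WT PBS replicate 4 (32.4 M, the others 31.4 to 31.6).

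The response to glycerol differed between the genotypes, by limma's test of the difference itself, in 79 genes. Of the genes examined by name the response was more positive in libraries labelled C3-/- for Nccrp1 (5.91), Kcnt1 (4.99), Rph3a (4.77), Vmn1r18 (4.23), Lypd2 (4.2), Ppp1r1b (3.54), Wfdc15b (2.91), Dusp15 (2.7) and Slc12a1 (2.55). It was more negative for Serpina6 (-7.9), Fut2 (-5.06), Cxcl5 (-4.89, the same as its difference after glycerol because all PBS libraries were listed at 0), Sox9 (-4.86), Fgg (-4.53), Chil3 (-3.93), Lif (-3.62), Serpina10 (-3.1), Ccl12 (-3.07), Pik3r1 (-2.39) and Anxa2 (-2.21). Leaving out 1 library ended the call for Vmn1r18 in 11 cases, Dusp15 in 11, Serpina6 in 13, Fgg in 11, Chil3 in 12, Ccl12 in 12, Anxa2 in 8 and Pik3r1 in 1. The largest adjusted p was 0.11 without WT PBS replicate 2 for Vmn1r18 and Fgg, 0.1 without the same library for Dusp15, 0.11 without C3-/- PBS replicate 3 for Serpina6, Chil3 and Ccl12, 0.067 without WT PBS replicate 4 for Anxa2 and 0.052 without C3-/- PBS replicate 2 for Pik3r1.

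The smaller injury response in libraries labelled C3-/- was weighed against 3 other explanations. Among list 1 libraries the tubule injury list still differed by a median of -1.53, which argues against the sheet list as its whole cause. The C3-/- glycerol libraries that carry Y-linked transcripts scored 8.73 (replicate 3, of list 2) and 10.87 (replicate 4). The lowest WT glycerol score lay 1.43 above the higher of these, against an SD of 0.3 in WT glycerol. This argues against sex as the source of these low scores. The gap is set by replicate 4 alone, so a part played by sex is not excluded. Of the 402 genes that differed after PBS, 370 lay on chromosomes other than that of C3, where they may respond to the C3 allele or differ through other loci of the genetic background. No library separates these, so effects of the C3 allele and of the background cannot be told apart.

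The genotype differences after PBS were also weighed. Of the 402 genes, 70.4% lay beyond the whole WT glycerol range in the same direction in both C3-/- glycerol libraries with Y-linked transcripts. Of other genes 14.1% did, which argues against sex as the cause of most of the 402. The check rests on 2 libraries, 1 of them of list 2. Genes that differ with sex also spread within C3-/- PBS, which mixes both kinds of library, and were less likely to be called. With the term for Y-linked transcripts alone 147 of the 402 kept call and direction, and 293 with the list and Y-linked terms. A part played by sex is thus not excluded. Within 20 Mb of C3 lay 8 of the 402 genes (2%), against 1.4% of all tested genes. A donor segment around C3 would thus hold few of these genes, which does not exclude that such a segment is present. Processed pseudogenes were more frequent among the genes higher in C3-/- (37 of 187; odds ratio 5.39, Fisher's exact p = 2.5e-14) and less among those lower (3 of 215; odds ratio 0.3, p = 0.02). Strain variants that move reads between gene copies are thus a candidate explanation for a part of the list, and an effect of the C3 allele stays open.

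The 3 list 2 libraries stood apart within both genotypes, and the shift from list 1 correlated between WT and C3-/- glycerol across genes (r = 0.76, genes not being independent replicates). limma gave 12112 genes a list 2 effect, 5309 higher and 6803 lower, and 97.2% as many after quantile normalization, which argues against the authors' scaling by 1 factor per library. The median effect on the tubule injury list was -0.74 (SE 0.29), and -0.21 (SE 0.29) without C3-/- glycerol replicate 3. The score of 8.73 in that library carried most of the effect (10.95 and 12.34 in the other 2). Each SE is over list members taken as independent and holds no spread between libraries. The median thus gave no sign of stronger injury in list 2, but with 3 libraries stronger injury is not excluded. Of 16 loop of Henle and distal tubule genes 8 were lower and 2 higher in list 2 (median -0.61), and of 15 collecting duct genes 8 lower and 4 higher (median -0.59), but neither list passed against other genes (camera adjusted p = 0.673 and 0.944; smallest of all lists 0.291). The effect correlated over genes with GC content (Spearman's rho = 0.41; -0.19 with exon length), so a difference in library preparation or sequencing is a candidate explanation, and no biological explanation other than injury was tested.

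Other splits of the libraries were fitted in the same way. For glycerol in WT, 1 of the 35 splits of the 8 libraries, the real one, gave 4666 genes (highest other 2). For glycerol in C3-/- it was also 1 of 35 (1016 genes, highest other 32), and for the genotypes after PBS 1 of 35 (402 genes; highest other 0 by limma, with at most 822 at an unadjusted p below 0.05). Ranking first is the most that 35 splits can show, and it does not exclude chance in these comparisons. For the genotypes after glycerol 6 of 35 splits gave as many genes as the real 2025 (highest other 8231), so chance was not excluded there either. The 5 others are the 5 splits that put the 3 list 2 libraries on 1 side, which points to the sheet list as a structure of the samples, and within list 1 the real comparison called 5432. For the difference in response 6 of 100 splits gave as many as the real 79 (highest other 2678), so chance was not excluded. Of the 5 others 2, the highest included, had the list 2 libraries on 1 side, and list 1 alone called 1858.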

How the results depend on the processing

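Fits with a term for Y-linked transcripts, or of libraries with them alone, were chosen after the data had been seen. Of 239 results for genes examined by name 218 passed the threshold. In the alternatives fixed beforehand 53 of these lost the call in at least 1 setting and 0 turned direction, by limma. Of 79 list results 14 lost the call in some setting and 0 turned. All these settings used camera with the preset correlation of 0.01. Most of the 79 list calls ended with the estimated correlation, which is not counted among them. Another scaling moved the median of all genes by at most 0.091 on the log2 scale. edgeR and DESeq2 on whole reads were not run here, because whole reads were not recovered. Depth is unknown, so no limit from depth is given. In the fit of the compared groups only, the log2 changes were those of the pooled fit, so only the estimate of spread moved the count. The pooled fit assumed the same spread of a gene in every group. The tubule injury score, however, had an SD of 0.05 in WT PBS and 1.08 in C3-/- glycerol. Pooled p-values may thus be too large between the PBS groups and too small where C3-/- glycerol is compared. Except where stated here or below, the cause of a moved count was not tested.

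For glycerol in WT the count of 4666 genes became 10902 with array weights, 8339 with a term for the sheet list, 10028 without list 2, 8886 with the list and Y-linked terms and 10474 with the Y-linked term without list 2 (3446 to 5360 leaving out 1 library).

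For glycerol in C3-/- the count of 1016 became 308 with the compared groups only, 5589 with array weights, 2608 with the list term, 4142 without list 2, 3393 with the list and Y-linked terms, 4410 with the Y-linked term without list 2 and 7 in libraries with Y-linked transcripts only. That last fit holds 1 C3-/- PBS library, assumed to vary like the other groups, and 47 of 50 calls examined by name ended in it. Without C3-/- PBS replicates 1, 2 or 3 the count was 492, 509 or 544, without WT glycerol replicate 4 2780, and without C3-/- glycerol replicates 1, 2 or 4 572, 1595 or 1568 (range 492 to 2780).

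For the genotypes after glycerol the count of 2025 became 1262 with a mean of at least 100, where fewer genes were tested, 297 with the compared groups only, 6439 with array weights, 5720 with the list term, 5432 without list 2, 6068 with the list and Y-linked terms, 4671 with the Y-linked term without list 2 and 798 in libraries with Y-linked transcripts only. It was 4396 without WT glycerol replicate 4 (range 1385 to 4396).

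For the genotypes after PBS the count of 402 became 203 with a mean of at least 100, where fewer genes were tested, 4579 with the compared groups only, 6869 with array weights, 1510 with the list term, 3481 without list 2, 157 with the Y-linked term, 628 with the list and Y-linked terms, 972 with the Y-linked term without list 2 and 51 in libraries with Y-linked transcripts only. Without WT PBS replicates 1 to 4 it was 255, 232, 232 and 220, without C3-/- PBS replicates 1 to 3 220, 234 and 238, and without WT glycerol replicate 4 609 (range 220 to 609).

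For the difference in response the count of 79 became 141 with a pseudocount of 8, 48 with a mean of at least 100, 3225 with array weights, 1324 with the list term, 1858 without list 2, 1580 with the list and Y-linked terms, 2283 with the Y-linked term without list 2 and, by limma, 0 in libraries with Y-linked transcripts only (870 at an unadjusted p below 0.05). Without WT PBS replicates 1 to 4 it was 43, 39, 41 and 40, without C3-/- PBS replicates 1 to 3 41, 38 and 40, without WT glycerol replicates 1 or 4 47 or 225, and without C3-/- glycerol replicate 1 179 (range 38 to 225).

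With the replicate block the counts were 3915 for WT, 632 for C3-/-, 1638 and 311 for the genotypes after glycerol and PBS, and 41 for the difference in response. Of 24 pairs of libraries with the same number 4 correlated above 0.1 (lowest -0.69, highest 0.38). In 15 of 48 comparisons a library was closest to its own number. No pairing by number was seen, which does not exclude one.

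The difference of C3 between the genotypes after glycerol, 0.07 and not called, turned to -1.1 with array weights, -0.32 with the list term, -0.78 without list 2, -0.14 with the Y-linked term, -0.54 with the list and Y-linked terms, -0.97 with the Y-linked term without list 2 and -0.03 in libraries with Y-linked transcripts only. Leaving out 1 library gave -0.37 (without C3-/- glycerol replicate 1) to 0.44, with -0.2 without WT glycerol replicate 2 and -0.19 without C3-/- glycerol replicate 3. For C3ar1 the same range was -0.97 to 0.07, the highest without C3-/- glycerol replicate 3, which turned its direction.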

Other observations

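Transcripts of red blood cells were lower in C3-/- than in WT kidney after PBS. Of 7 genes 4 were lower (5 adjusted over the list alone; median -1.5, camera adjusted p = 6.29e-08, and 0.0187 with an estimated correlation). Alas2, the erythroid enzyme of heme synthesis, averaged 221.8 ± 46.35 in WT PBS and 64.83 ± 19.7 in C3-/- PBS (n = 4 each), a log2 difference of -1.79 ± 0.35 (limma adjusted p = 0.011; -1.63 with adjusted p = 0.18 with the term for Y-linked transcripts). After glycerol 3 of the 7 rose in libraries labelled C3-/- (4 adjusted over the list alone; median 1.03, adjusted p = 0.00125; adjusted p = 0.121 with an estimated correlation), Alas2 by 1.83 ± 0.35 (adjusted p = 0.0061; 1.92 with adjusted p = 0.82 in libraries with Y-linked transcripts only). In WT limma called none of the 7, with 0 at an unadjusted p below 0.05 (median 0.07, adjusted p = 0.944).

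Clock genes differed between the genotypes after glycerol. Of 15 genes 8 were higher and 1 lower in libraries labelled C3-/- (9 and 2 adjusted over the list alone; median 1.04, adjusted p = 0.00281; adjusted p = 0.0638 with an estimated correlation). The transcription factor gene Tef was higher by 1.84 ± 0.33, and the period gene Per3 by 1.73 ± 0.33, while Npas2 was lower by -1.59 ± 0.29 (adjusted p = 0.002, 0.0031 and 0.0024; 0.08, 0.095 and 0.055 in a fit of these 8 libraries alone). In WT 5 of the 15 fell after glycerol (5 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.0243, and 0.141 with an estimated correlation). Within list 1, 8 fell and 1 rose there (median -0.65, camera adjusted p = 0.032). In libraries labelled C3-/- 2 rose after glycerol (3 rose and 1 fell adjusted over the list alone), and the list did not pass (median -0.24, camera adjusted p = 0.808). The hour of sampling is not in the labels. The immunoglobulin light chain gene Igkc averaged 187.2 ± 188.3 in WT glycerol and 2952 ± 3079 in C3-/- glycerol libraries (3.97 ± 0.77, adjusted p = 0.0038; 3.14 with adjusted p = 0.092 in libraries with Y-linked transcripts only). The lymphocyte list as a whole did not differ after glycerol (median 0.21, adjusted p = 0.714) and was lower in C3-/- after PBS (median -0.61, adjusted p = 6.17e-06, and 0.0187 with an estimated correlation; limma called none of 15 genes, 2 adjusted over the list alone, with 5 lower at an unadjusted p below 0.05).

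Some abundant transcripts separated list 2 from list 1 in every library, and were chosen after their values were seen. Gapdh lay between 27500 and 36700 in list 1 and between 128000 and 167000 in list 2, Lars2 between 7960 and 21100 and between 70800 and 96800, and the mitochondrial ribosomal RNA mt-Rnr2 between 28500 and 170000 and between 283000 and 715000. Eef1a1 was lower in list 2 (52300 to 57800, against 104000 to 149000). Malat1 overlapped (44600 to 103000 in list 1, 63900 to 370000 in list 2).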
